A study of Mus musculus with 6 samples.

How the data were processed

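The study profiled single cells of the posterior eye of mice given tropicamide or saline eye drops, in 6 libraries of 4 pooled right eyes each, 3 per group. The deposited matrices hold the UMI count of each gene in each cell barcode, without normalization, made with Cell Ranger 8.0.1 per the file headers. Alignment with STAR to the mouse build GRCm39 is stated per the submitters' processing notes, and the annotation release, the counting of intron reads and the cell-calling settings are not given in the sources used here. The extraction protocol in the labels describes bone tissue and cell sorting and was not used. The matrices hold 33696 genes, of which 26 symbols are shared by more than 1 gene ID, and every barcode has at least 500 UMIs. The 6 libraries held 9499, 13518 and 12704 barcodes for tropicamide and 9472, 10445 and 10796 for saline.

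Barcodes with at least 500 UMIs, at least 300 genes and at most 20% mitochondrial UMIs were kept, which removed 416 of 66434. Doublets were scored per library against 2 simulated doublets per barcode with 50 neighbours, and the top 0.8% per 1000 barcodes were removed, 5922 in all. Log counts scaled to 10000 per cell, 2000 variable genes, 30 principal components and 20 neighbours were used for Leiden clustering at resolution 1 in 2 rounds, the second on the cells outside the 11 clusters kept from the first. A cluster was named from 29 marker lists where its best score was at least 0.7 with at least 3 markers detected. Where at least 2 of its top 10 genes were markers of 1 list, that list gave the name instead, which applied to cluster B27, and a cluster with more markers of another list than of its own among its top 10 genes stayed unnamed, as A26 and B33 did. A named cluster is called by that name with the ending "-like". Free RNA from lysed cells was not removed. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9.

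Counts were summed per library and class, so that the pool of 4 eyes is the replicate. The 8 classes with at least 30 cells in every library, and all cells summed, were compared (tropicamide over saline) with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with TMM normalization, the filterByExpr filter and a Benjamini-Hochberg adjusted p under 0.05 within class. Per-gene adjusted p values in the text are from edgeR unless another tool is named. The 34 gene lists were tested with camera of limma 3.58.1 at a preset correlation between genes of 0.01, adjusted over the 242 class and list pairs with at least 5 tested members, of which 92 passed. All 92 lost their call when the correlation was estimated per list, at adjusted p values of at least 0.47. For 46 of the 92 the result is described below, and the others appear only among the list tests chosen later or not at all. Shares of cells were compared for the 16 classes with at least 100 cells by a two-sided exact permutation test on logit shares, with 20 arrangements and a smallest p of 0.1. The difference between the change in a class and that in rods was tested with limma.

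Named genes follow a rule. Per class, among genes past the threshold with a mean CPM of at least 20 and groups that do not overlap, the 6 highest and the 6 lowest log2 fold changes were named. For each list past the threshold up to 4 members of smallest p in its direction could be named, and where no gene passed the 3 genes of smallest p. Chrm1 to Chrm5 and Egr1 were always examined, and genes with clone-like names were not named. Some genes that the rule picks are not reported here. The groups, filters, marker and gene lists, tests, this rule and the first set of alternatives were chosen before the data were examined. List tests chosen later were adjusted among themselves. The limits for naming a cluster were set after the clusters and their top genes were seen. Genes and tests chosen later are said to be so where they appear.

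Alternatives were DESeq2 1.42.0 size factors in edgeR, the DESeq2 test, no low-count filter, the replicate number as a block, each library left out in turn, a stricter cell filter (1000 UMIs, 500 genes, 10% mitochondrial), no doublet removal, other tests of lists and shares, and a denominator without rods. Restrictions to some clusters of a class, to rods drawn to the same number per bin of UMIs in every library, to genes at least as high in rods, and 6 classes with at least 10 cells in every library were added after seeing the data.

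The tests were checked on simulated data with 200 changed genes. For 2-fold changes edgeR recovered 85.1% in rods, 74.6% in fibroblast-like cells, 68.7% in B5, 55.2% in Müller glia-like cells and in B2, 49.3% in retinal pigment epithelium-like cells, 47.8% in endothelial-like cells and 43.3% in cone bipolar-like cells, and for 1.5-fold changes 61.2% in rods and 3% in cone bipolar-like cells. The share of false calls was 1.8% to 7.8% in edgeR and up to 10.9% in DESeq2, the latter with all cells summed (9.3% in corneal or conjunctival epithelium-like cells). A list shifted by 0.5 on the log2 scale was called in every class tested, and 1 other list was called in B5 and 1 in retinal pigment epithelium-like cells. The simulated genes were drawn independently of each other, so this check does not cover false calls of lists whose members vary together. In the real libraries another split into 3 and 3 gave 75 class and list pairs, against 92 in the real one. The spread between replicates of a group was 1.3 to 61.6 times that of counting alone (chi-square per degree of freedom). Coordinates were not used.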

Results

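Single-cell RNA sequencing was used to compare the back of the mouse eye under a relaxed and a working ciliary muscle, in a study of how this muscle bears on the onset of myopia. Tropicamide, a muscarinic receptor antagonist used in the clinic to dilate the pupil and relax accommodation, was dropped onto the eyes of 1 group of 12 mice at intervals of 10 min for 6 drops, and the tissue was taken 1 h later. The other 12 mice received saline drops at the same interval, and the labels give neither the number of drops nor a waiting time for them. Each library pooled the right eyes of 4 mice, so that each group had 3 pools, and the tissue was the posterior cup of sclera, choroid and retina. The files held 66434 barcodes and 229624062 UMIs (unique molecular identifiers, each marking 1 captured transcript). The 3 tropicamide pools held 37373428, 49477707 and 39804355 UMIs, and the 3 saline pools held 30761887, 31308887 and 40897798. Median UMIs per barcode were 2336, 2321 and 2189 in the tropicamide pools and 2341, 2355 and 2528 in the saline pools. After filters and doublet removal 60096 cells were kept, 8718, 11998 and 11316 after tropicamide and 8705, 9546 and 9813 after saline.

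The cells fell into 53 clusters, of which 45 were given 1 of 19 names from markers fixed beforehand and 8 stayed unnamed. Rod-like cells (50479) made up most of the data, followed by fibroblast-like (2615), retinal pigment epithelium-like (1719), endothelial-like (987), Müller glia-like (498), cone-like (436) and cone bipolar-like cells (363). The largest unnamed clusters were B2 (751 cells), led by Smoc1, Serpine2, Angpt1 and Pgf, and B5 (503 cells), led by Ptn, Schip1, Edn3, Wnt10a and Wnt6. The 8 unnamed clusters together held a mean of 3.48% of the cells in the tropicamide pools and 1.78% in the saline pools. Corneal or conjunctival epithelium-like and ciliary or iris epithelium-like cells were present at 198 and 80 cells, although these tissues had been excised.

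The share of recovered cells per class was compared between the groups. The dissection sets the shares of the classes outside the retina, so these shares do not measure numbers of cells in the eye. Retinal pigment epithelium-like cells, the pigmented layer that supports the photoreceptors, made up 4.24% ± 1.26 of cells after tropicamide and 1.12% ± 0.482 after saline (SD, n = 3 pools per group), 3.8 times the share. Melanocyte-like cells, the pigment cells of the choroid, made up 0.360% ± 0.236 and 0.0688% ± 0.0315, 5.225 times the share. They numbered 52, 43 and 14 in the tropicamide pools and only 9, 4 and 6 in the saline pools. In both classes every tropicamide pool lay above every saline pool, which gave p = 0.1 in a two-sided exact permutation test, the smallest value that 3 against 3 pools allow. The adjusted p was 0.533 over the 16 classes compared, so no share passed. Among cells that are not rods the log2 ratio was 1.33 for retinal pigment epithelium-like cells (1.93 among all cells) and 1.52 for melanocyte-like cells (2.385 among all cells). Rod-like cells made up 80.3% ± 4.62 and 87.95% ± 4.35 of cells (exact p = 0.2), fibroblast-like cells 4.92% ± 1.17 and 3.77% ± 1.12 (exact p = 0.3), and Müller glia-like cells 0.668% ± 0.0958 and 1.04% ± 0.444 (exact p = 0.2). The ratio of retinal pigment epithelium-like to fibroblast-like cells was 0.921 ± 0.407 after tropicamide and 0.290 ± 0.0465 after saline (exact p = 0.1). Median UMIs per melanocyte-like cell were 1057 to 1436 in the tropicamide pools and 3552 to 10340 in the saline pools, the latter over 4 to 9 cells per pool. Those of retinal pigment epithelium-like cells overlapped, at 1589 to 1643 and 1594 to 1796.

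**Figure D1:**
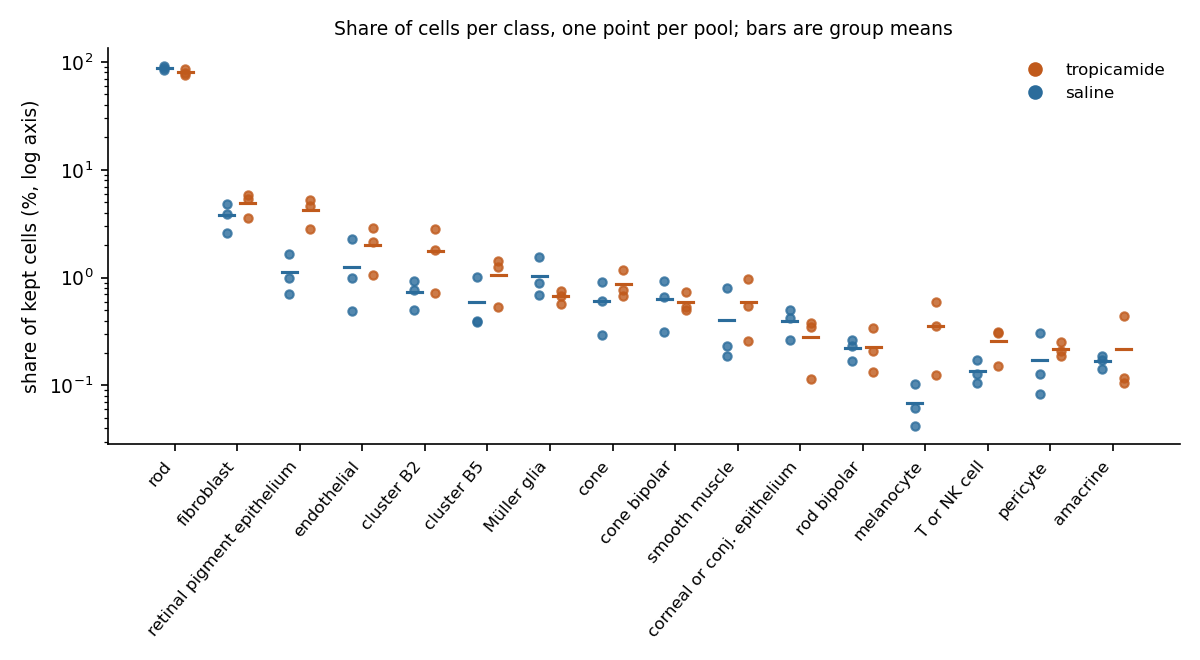
Share of all kept cells (%, log axis) per class, with 1 point per pool and bars at the group means. The 3 tropicamide pools lie above the 3 saline pools for the retinal pigment epithelium (means 4.24% and 1.12%) and the melanocytes (0.360% and 0.0688%).

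In rod-like cells, the dim-light photoreceptors, Yars, which charges tRNA with tyrosine, fell from 102.3 ± 10.7 to 53.8 ± 0.251 CPM (counts scaled to library depth; SD, n = 3 pools per group), a log2 fold change of -0.93 ± 0.07 (SE; edgeR adjusted p = 1.9e-05). Cars and Iars, which load cysteine and isoleucine, fell by 0.81 and 0.71 on the log2 scale. Mthfd2, an enzyme of mitochondrial folate metabolism, fell by 1.05, Aldh18a1, an enzyme of proline synthesis, by 0.85, and Atf3, a stress-induced transcription factor, by 0.68 (adjusted p of 6.37e-05 to 0.0012). Peg3, an imprinted zinc finger gene, rose from 127.2 ± 1.41 to 194.6 ± 12.7 CPM (log2 fold change 0.61 ± 0.05, edgeR adjusted p = 3.89e-05), and Gas7 and Selenbp1 rose by 0.68 and 0.63. Ptgds, a prostaglandin D synthase, rose by 2.10 ± 0.35 (edgeR adjusted p = 0.0365) and Apoe, a lipid carrier, by 1.06 ± 0.20 (adjusted p = 0.0398). Ptgds stood at 132.1 ± 26.1 CPM in the rods of the tropicamide pools, against 79170 ± 2789 CPM in their retinal pigment epithelium-like cells.

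**Figure D2:**
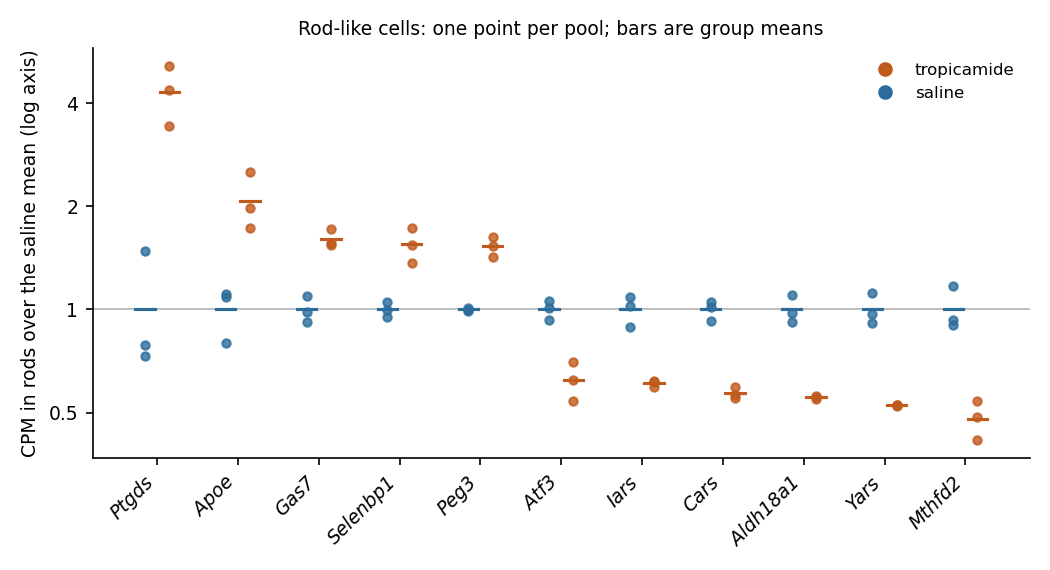
CPM in rod-like cells divided by the saline mean (log axis) for the named genes of highest and lowest log2 fold change, with 1 point per pool and bars at the group means. Mthfd2 and Yars fell by 1.05 and 0.93 on the log2 scale. The genes were chosen among those whose groups do not overlap, so the 3 tropicamide pools lie apart from the 3 saline pools by choice.

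Of the gene lists fixed beforehand, 9 passed camera's test in rods. The photoreceptor's own light-response list gave 20 of 22 members above 0 and 5 that rose (5 adjusted over the list alone), among them Slc24a1, the rod sodium-calcium exchanger, by 0.32, and Cngb1 and Cnga1, the channel subunits, each by 0.19. Of 15 visual cycle genes 4 rose (8 adjusted over the list alone), among them Rdh12 by 0.28, Lrat by 2.46 and Stra6 by 1.03. Of 13 glucocorticoid-responsive genes 3 rose (5 adjusted over the list alone), namely Tsc22d3 by 0.45, Klf9 by 0.23 and Nfkbia by 0.21. Of 28 genes tied to refractive error and myopia 3 rose (5 adjusted over the list alone), namely the growth factor gene Igf1 by 1.10, the cone arrestin gene Arr3 by 0.50 and the collagen hydroxylase gene P4ha2 by 1.10. Of 15 inflammatory genes 2 rose, Nfkbia and the chemokine gene Cxcl10 by 0.76 (4 adjusted over the list alone). The adjusted p of these 5 lists was 6.88e-06 to 0.0407, and 0.47 to 0.622 with an estimated correlation. Within the largest rod cluster, A0, a restriction chosen after seeing the data, the light-response, glucocorticoid and inflammatory lists did not pass limma's camera. The first had 14 of 22 members above 0 and a mean of 0.04 (0.10 over all rods; limma adjusted p = 0.0704), the second a mean of 0.23 (0.29 over all rods; adjusted p = 0.0701), and the last, with 9 members tested, a mean of 0.22 (0.34 over all rods; adjusted p = 0.128).

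The other 4 lists that passed in rods were matrix, immune and pigment lists. Of 24 collagens and matrix genes, all above 0, 5 rose (7 adjusted over the list alone), among them Loxl1 by 0.91, Thbs1 by 1.28 and Fbn1 by 1.22. Of 17 antigen presentation and complement genes, all above 0, 5 rose (6 adjusted over the list alone), among them the class II genes H2-Ab1 by 2.89 and Cd74 by 2.55, at 2.16 and 4.27 CPM after tropicamide. Of 17 matrix remodelling genes 4 rose (7 adjusted over the list alone), among them the proteases Mmp3 by 1.34 and Mmp2 by 0.55. Of 7 melanogenesis genes 4 lay above 0 and none rose in edgeR (2 adjusted over the list alone). The adjusted p of these 4 lists was 1.62e-09 to 0.0495, and 0.47 to 0.572 with an estimated correlation. Some transcripts of other cell types were more abundant in the rods of the tropicamide pools: Ttr, a retinal pigment epithelium transcript, at 83.6 to 200.1 CPM against 19.7 to 45.2, Dcn, a fibroblast transcript, at 86.6 to 154.7 against 49.5 to 91.1, and the haemoglobin gene Hba-a1 at 8.76 to 347.8 against 0.663 to 3.25. Krt12, a corneal epithelium transcript, was not, at 28.3 to 39.1 CPM against 15.8 to 47.1. Of the 999 genes higher after tropicamide 186 were at least 3 times higher outside the rods, as were 62 of the 903 lower and 3185 of the 16423 tested. Of the genes named above as higher in rods, Ptgds is among the top 10 genes of the retinal pigment epithelium-like clusters B0 and B3, Lrat of the retinal pigment epithelium-like cluster B18 and the unnamed A26, Arr3 of the cone-like clusters B11 and B26, Igf1 of the unnamed clusters B5 and B36, Cd74 of the B cell-like cluster B40 and Mmp3 of the fibroblast-like cluster B13.

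In all, 1902 of 16423 genes passed in rods, 999 higher and 903 lower after tropicamide, and DESeq2 passed 1514. Of the 1902, 177 changed by over 1 on the log2 scale, and the median size was 0.33. The groups did not overlap for 32.1% of the genes tested, where chance gives 10% on average. A single split can lie away from that average when genes vary together, and this share was not taken for the other splits in any class. The count was 1179 without saline replicate 1, 1108 without saline replicate 2, 1098 without tropicamide replicate 1 and 529 without tropicamide replicate 2. Of the 42 called rod genes examined in this way, Yars, Cars, Iars, Mthfd2, Aldh18a1, Atf3, Peg3, Gas7 and Selenbp1 were among the 24 that passed without each library in turn, while the others did not. In edgeR, Ptgds lost its call without each library but saline replicate 3 (adjusted p of up to 0.135), and Apoe without saline replicates 1 and 3 and tropicamide replicate 1 (up to 0.112). P4ha2 lost its call without each library but saline replicate 3 (edgeR adjusted p of up to 0.161), and Arr3 without saline replicates 1 and 2 and tropicamide replicates 1 and 3 (up to 0.105). Cnga1, Cxcl10, Nfkbia, Cngb1, Klf9, Stra6, Fbn1, Thbs1 and Mmp2 also lost theirs without at least 1 library, at edgeR adjusted p values of up to 0.133, 0.174, 0.118, 0.0869, 0.135, 0.154, 0.0854, 0.075 and 0.0602. Leaving out tropicamide replicates 1, 2 and 3 ended the call of 13, 16 and 11 of the 42 genes, and leaving out saline replicates 1, 2 and 3 that of 13, 14 and 1. Rods of the largest rod cluster alone gave 1194 genes. Cluster A1 held 10.1% to 12.6% of the rods in the tropicamide pools and 19.2% to 22.8% in the saline pools, and cluster A3 held 12.7% to 17.8% and 5.04% to 8.0%.

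In Müller glia-like cells, the supporting glia of the retina, Fkbp5, a co-chaperone gene induced by glucocorticoids, rose from 83.2 ± 7.67 to 202.1 ± 40.8 CPM (SD, n = 3 pools per group), a log2 fold change of 1.30 ± 0.21 (SE; edgeR adjusted p = 0.0029). Cxcl1, a neutrophil-attracting chemokine gene, fell from 119.8 ± 32.7 to 13.5 ± 8.46 CPM (-3.07 ± 0.37, edgeR adjusted p = 8.96e-05), and Rnaseh2a, a subunit of an RNase that clears RNA from DNA, fell from 195.8 ± 64.3 to 37.4 ± 11.7 CPM (-2.39 ± 0.30, adjusted p = 0.000151). Socs3, an inhibitor of cytokine signalling, fell by 1.35 (edgeR adjusted p = 0.00187), Junb, Egr1 and Btg2, early response genes, by 0.84, 0.67 and 0.63, and the inflammation-linked factor gene Cebpd by 0.54. Fbxl18, Slc25a21, Nfe2l3 and Trim17 fell by 2.28, 1.94, 1.79 and 1.67. Zbtb16 and Sgk1, also glucocorticoid targets, rose by 1.06 and 1.21. The photoreceptor genes Rbp3 and Cngb1 rose by 1.28 and 1.27, Col1a2, a fibroblast collagen gene, by 1.31 and the kinase gene Mast3 by 1.25.

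Of the gene lists, 11 passed in Müller glia-like cells. All 48 cytosolic ribosomal protein genes lay above 0 and 26 rose (48 adjusted over the list alone), with Rpl3 at 0.93 and Rplp1 at 0.82. All 21 rod phototransduction genes lay above 0 and 12 rose (19 adjusted over the list alone), with Gngt1 at 1.00 and Gnat1 at 0.89. All 13 mitochondrially encoded genes lay above 0 and 5 rose (9 adjusted over the list alone), with mt-Co2 at 0.82 and mt-Nd4 at 0.72. Of 44 nuclear oxidative phosphorylation genes 3 rose (17 adjusted over the list alone), with Uqcrh at 0.73, and of 8 visual cycle genes only Rbp3 rose (4 adjusted over the list alone). Of 23 immediate early genes, those named above, 3 fell (11 adjusted over the list alone), of 7 gliosis genes Socs3 and Cebpd fell (2 adjusted over the list alone), and of 6 inflammatory genes Cxcl1 and Nfkbiz, the latter by 0.66, fell (2 adjusted over the list alone). Of 13 glucocorticoid-responsive genes 3 rose and 1 fell (the same counts adjusted over the list alone), with an adjusted camera p of 0.0186 for the list. Among the list tests chosen after values were seen, its adjusted camera p was 0.0118, and 0.113 without Fkbp5. Without Fkbp5 the list still passed camera within cluster B10 of this class (adjusted p = 0.0188). It also passed in rods (0.00513), endothelial-like cells (0.000117) and all cells summed (0.000279). With an estimated correlation none of these passed, at adjusted p values of 0.16 to 0.553. Of 14 myopia genes Tox, a chromatin factor, and Egr1 fell by 0.64 and 0.67 (3 adjusted over the list alone), and of 13 synaptic genes, 10 of them above 0, none rose and 1 fell in edgeR (4 rose adjusted over the list alone). The adjusted p of the 11 lists was 2.37e-46 to 0.0213, and 0.47 to 0.551 with an estimated correlation.

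**Figure D3:**
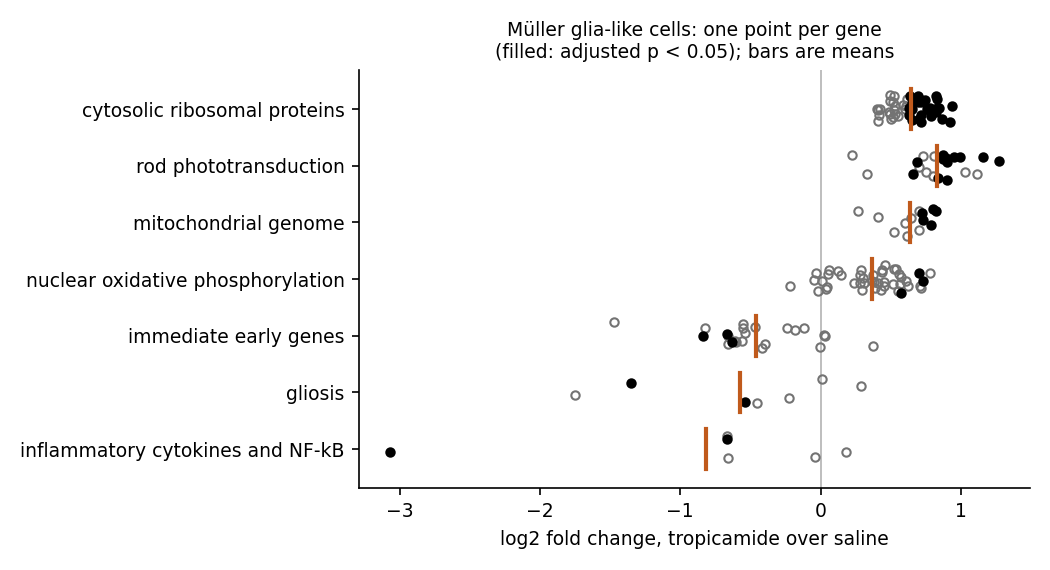
Log2 fold change (tropicamide over saline) in Müller glia-like cells of the members of 7 gene lists, with 1 point per gene, filled where the adjusted p passed 0.05, and bars at the list means. All 48 ribosomal protein genes lie above 0, and 20 of the 23 immediate early genes lie below 0.

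In all, 148 of 6898 genes passed in Müller glia-like cells, 97 higher and 51 lower, and DESeq2 passed 156. The groups did not overlap for 19.6% of the genes, where chance gives 10% on average. The count was 4 without saline replicate 1, 50 without saline replicate 2 and 23 without tropicamide replicate 3, and of the 29 called genes examined in this way, Cxcl1, Rnaseh2a and Socs3 passed without each library in turn. The other 26 each lost the call without at least 1 library, at highest edgeR adjusted p values of 0.0559 (Fbxl18) to 0.343 (Nfkbiz). Leaving out tropicamide replicates 1, 2 and 3 ended the call of 5, 13 and 21 of the 29, and leaving out saline replicates 1, 2 and 3 that of 25, 15 and 3, with Fkbp5 at an adjusted p of 0.0626 without saline replicate 1. The class joins clusters B10 and B20, and B20 (median 1013 UMIs, 9.04% mitochondrial) held 47.0% to 58.4% of the class in the tropicamide pools and 22.4% to 30.3% in the saline pools. Median UMIs per Müller glia-like cell were 1239 to 2003 after tropicamide and 4933 to 7459 after saline. Cells of B10 alone gave 44 genes, 21 higher and 23 lower, those of B20 alone none of 494 in edgeR (15 at an unadjusted p under 0.05, and none in DESeq2), and the stricter cell filter gave 64.

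Fibroblast-like cells and the unnamed clusters B2 and B5 were compared next. In cluster B2 Fkbp5 rose from 120.9 ± 31.5 to 275.6 ± 35.1 CPM (SD, n = 3 pools per group; log2 fold change 1.20 ± 0.17, edgeR adjusted p = 0.0132). Sox9, a transcription factor of cartilage and matrix-forming cells, fell by 0.98 (edgeR adjusted p = 0.0132), the interferon-induced chemokine gene Cxcl10 by 0.79 (adjusted p = 0.015) and Tmtc2 by 0.96 (adjusted p = 0.0447). In cluster B5 Fkbp5 rose by 1.03 ± 0.18 (edgeR adjusted p = 0.0442), as did the p53-induced gene Trp53inp1 by 1.32, Kansl1l by 1.26, Tex14 by 1.21 and the oxidase gene Aox4 by 1.15. The monocyte-attracting chemokine gene Ccl2 fell from 740.7 ± 132 to 376.8 ± 17 CPM in B5 (-0.99 ± 0.13, edgeR adjusted p = 0.00614), the polyamine enzyme gene Odc1 by 0.65 and the flow-responsive factor Klf2 by 0.58. In fibroblast-like cells the histone gene H1f2 rose by 0.82, and Esr1, the oestrogen receptor gene, Tmeff2 and the transcription factor gene Sox4 fell by 0.88, 0.82 and 0.82 (adjusted p of 0.0324 to 0.0459). Bmpr1b, a BMP receptor gene named after its values were seen because the count is only 5, fell by 1.22 (edgeR adjusted p = 0.0324).

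Early response and inflammatory lists lay below 0 in fibroblast-like cells, B2 and B5. Of the immediate early genes 23 of 24 in B2, 21 of 24 in B5 and 24 of 25 in fibroblast-like cells were below 0, with none, 1 (Klf2) and none that fell (8, 4 and none adjusted over the list alone). Members that did not pass included Klf2 in B2 (-0.53, edgeR adjusted p = 0.079) and Egr3 in fibroblast-like cells (-0.64, adjusted p = 0.197). All 13 inflammatory genes tested lay below 0 in each class, with means of -0.44, -0.45 and -0.64, and 1 (Cxcl10), 1 (Ccl2) and none fell (3, 1 and none adjusted over the list alone). Interferon response genes lay below 0 for 16 of 20 members in B2 and 18 of 20 in fibroblast-like cells, where Gbp2 stood at -0.96 and Rnf213 at -0.86 without passing (1 and 4 fell adjusted over the list alone). Unfolded protein response genes lay above 0 for 12 of 16 members in fibroblast-like cells, with the chaperone-related genes Creld2 at 0.84 (edgeR adjusted p = 0.0653) and Manf at 0.51 (adjusted p = 0.0679) (4 rose and 1 fell adjusted over the list alone). Of 13 glucocorticoid-responsive genes in B2 only Fkbp5 rose (4 adjusted over the list alone), with an adjusted camera p of 0.0193 for the list. Among the list tests chosen after values were seen, its adjusted camera p was 0.0124, and 0.266 without Fkbp5. In B5 12 of 13 mitochondrially encoded genes lay below 0 (5 fell adjusted over the list alone). Rod phototransduction genes lay above 0 for 20 of 20 members in B2, 17 of 20 in B5 and 21 of 22 in fibroblast-like cells (2, none and none rose adjusted over the list alone). The adjusted p of these 14 lists was 2.5e-13 to 0.0193, and 0.47 to 0.671 with an estimated correlation. Among the list tests chosen after values were seen, ribosomal protein genes lay below 0 for 48 of 48 members in fibroblast-like cells. Their mean was -0.09 (camera adjusted p = 0.00738, or 0.792 with an estimated correlation).

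**Figure D4:**
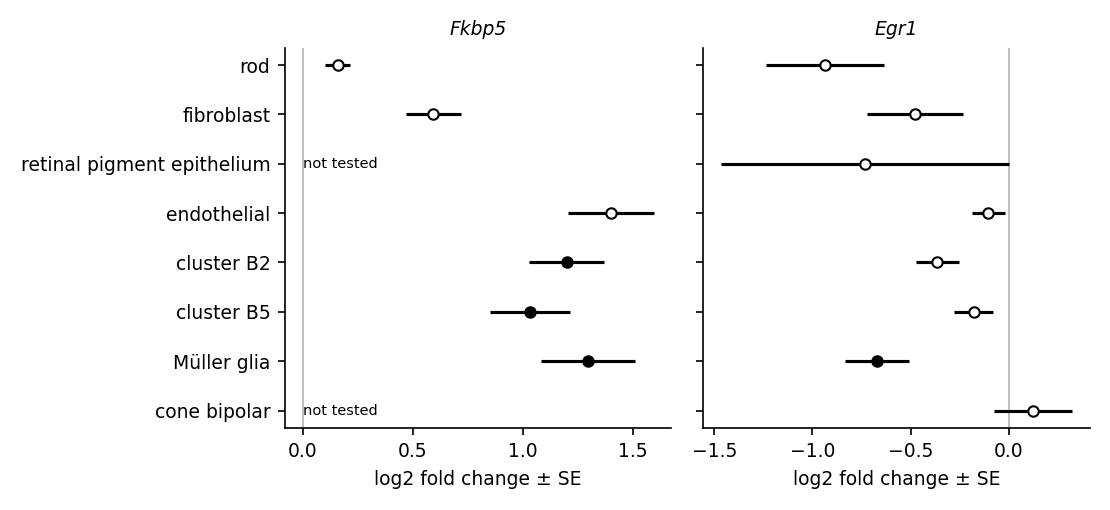
Log2 fold change (tropicamide over saline) ± SE of Fkbp5 and Egr1 per class, filled where the adjusted p passed 0.05. Fkbp5 rose in Müller glia-like cells (1.30), cluster B2 (1.20) and cluster B5 (1.03), and Egr1 fell in Müller glia-like cells (-0.67).

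In all, 4 of 8597 genes passed in B2 (30 in DESeq2), 9 of 8468 in B5 (20 in DESeq2) and 5 of 13815 in fibroblast-like cells (148 in DESeq2). The groups did not overlap for 13.2%, 12.8% and 18.3% of genes, where chance gives 10% on average. The count in B2 was 0 without saline replicate 1 and without tropicamide replicate 2, 15 without saline replicate 3, 9 without tropicamide replicate 1 and 2 without tropicamide replicate 3. That in B5 was 20 without saline replicate 3, 1 without tropicamide replicate 2 and 0 without tropicamide replicate 3, and that in fibroblast-like cells was 236 without tropicamide replicate 3 and 0 without each of the other libraries. None of the called genes of these 3 classes passed without each library in turn. In edgeR, Fkbp5 had an adjusted p of 0.0516 in B2 without saline replicate 1 and 0.191 without tropicamide replicate 2. In B5 its call ended without each library but saline replicate 3, at edgeR adjusted p values of up to 0.206. Cluster B1 held 16.2% to 37.8% of the fibroblast-like cells in the tropicamide pools and 33.8% to 39.9% in the saline pools, and cluster B15 held 6.14% to 12.4% and 4.42% to 5.24%. The lists were not tested within these clusters.

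In retinal pigment epithelium-like cells Gpnmb, a melanosomal glycoprotein gene, fell from 570.0 ± 122 to 274.1 ± 41.8 CPM (SD, n = 3 pools per group; log2 fold change -1.04 ± 0.12, edgeR adjusted p = 2.82e-08). Pcolce, an enhancer of procollagen processing, fell by 0.68 ± 0.12 (edgeR adjusted p = 0.000149), and Ddx5, an RNA helicase gene, rose from 636.6 ± 113 to 985.6 ± 48.5 CPM (0.59 ± 0.10, adjusted p = 6.39e-05). Melanogenesis genes lay below 0 for 9 of 10 members (none fell in edgeR over all genes, 3 adjusted over the list alone), with the pigment enzyme gene Tyrp1 at -0.54 (adjusted p = 0.107). Rod phototransduction genes lay above 0 for 18 of 22 members and heat shock genes for 8 of 10 (1 and none rose adjusted over the list alone). The adjusted p of these 3 lists was 2.25e-06 to 0.00464, and 0.47 with an estimated correlation. Of 5226 genes 3 passed, and 3 in DESeq2. The groups did not overlap for 13.7% of genes, where chance gives 10% on average. The count was 10 without saline replicate 1, 17 without saline replicate 3, 20 without tropicamide replicate 1 and 5 without tropicamide replicate 3, and Pcolce had an adjusted p of 0.0533 without tropicamide replicate 2.

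In endothelial-like cells, the lining of the vessels, no gene of 10376 passed in edgeR, against 692 at an unadjusted p under 0.05 and 21 passing in DESeq2. The smallest p values belonged to Fkbp5 (log2 fold change 1.40 ± 0.20, edgeR adjusted p = 0.0638; 157.6 ± 20.4 against 52.8 ± 22.8 CPM, SD, n = 3 pools per group), the transporter gene Slc10a6 (2.03 ± 0.32, adjusted p = 0.0638) and Nbl1, a BMP antagonist gene (1.24 ± 0.20, adjusted p = 0.0665). Collagens and matrix genes lay above 0 for 15 of 17 members, with elastin (Eln) at 0.62, and glucocorticoid-responsive genes for 11 of 14 (2 and 3 rose and 1 and none fell adjusted over the list alone). Immediate early genes lay below 0 for 21 of 25 members, with Jun at -0.52, and inflammatory genes for 12 of 13 (6 and none fell adjusted over the list alone). The fibroblast transcript Dcn stood at 89.3 to 158.8 CPM in the endothelial-like cells of the tropicamide pools and 38.7 to 88.4 in those of the saline pools, and Ttr at 97.4 to 130.9 and 9.78 to 46.6. The adjusted p of these 4 lists was 9.11e-08 to 0.00574, and 0.47 with an estimated correlation. Cluster B6 held 55.0% and 56.2% of the class in tropicamide replicates 1 and 2 and 44.3% in saline replicate 3, and B9 held 50.8% in tropicamide replicate 3 and 58.6% and 53.2% in saline replicates 1 and 2. B6 alone gave 3 genes and B9 alone 7. The immediate early genes lay below 0 for 11 of 23 members in B6 alone, with a mean of -0.05 (camera adjusted p = 0.899), and for 18 of 22 in B9 alone, with a mean of -0.27 (camera adjusted p = 8.08e-12, or 0.322 with an estimated correlation). The inflammatory genes had a mean of -0.29 in B6 alone, without passing (camera adjusted p = 0.144), and of -0.58 in B9 alone (camera adjusted p = 1.66e-05, or 0.322 with an estimated correlation). These tests were chosen after seeing the data. The count was 14 without saline replicate 3, 9 without tropicamide replicate 1, 31 without tropicamide replicate 3 and 1 without saline replicate 2.

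In cone bipolar-like cells, which relay cone signals, no gene of 6517 passed in edgeR, against 265 at an unadjusted p under 0.05 and 1 passing in DESeq2. The smallest p values belonged to the phosphodiesterase gene Pde10a (488.5 ± 21.8 against 175.8 ± 85.2 CPM; SD, n = 3 pools per group; log2 fold change 1.36 ± 0.23, edgeR adjusted p = 0.0571), the retinal pigment epithelium transcript Ttr (1.93, adjusted p = 0.0571), which was higher after tropicamide in rods too, and the Notch coactivator gene Maml2 (-1.29, adjusted p = 0.0617). Hypoxia-responsive genes lay above 0 for 16 of 17 members and nuclear oxidative phosphorylation genes below 0 for 38 of 44, with means of 0.25 and -0.14 (none of either passed adjusted over the list alone). Their adjusted p was 0.00104 and 0.00787, and 0.47 and 0.551 with an estimated correlation. Among the list tests chosen after values were seen, glucocorticoid-responsive genes lay above 0 for 8 of 9 members, with a mean of 0.35. Mitochondrially encoded genes lay below 0 for 9 of 11, with a mean of -0.16. Their camera adjusted p was 0.00302 and 0.0376, and 0.16 and 0.644 with an estimated correlation. The count was 19 without saline replicate 3, 4 without tropicamide replicate 3 and 1 without saline replicate 2.

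With all cells summed, 2 of 20089 genes passed, both lower after tropicamide, and DESeq2 passed 538. Prss22, a serine protease gene of surface epithelia, fell from 44.0 ± 10.6 to 0.513 ± 0.1 CPM (SD, n = 3 pools per group; log2 fold change -6.42 ± 0.25, edgeR adjusted p = 0.000819). Chac1, a glutathione-degrading enzyme gene named after its values were seen, fell from 12.95 ± 5.10 to 0.375 ± 0.140 CPM (-5.11 ± 0.40, edgeR adjusted p = 0.0416). Melanogenesis genes lay above 0 for 10 of 10 members, collagens for 25 of 25 and visual cycle genes for 12 of 16 (8, none and 9 rose adjusted over the list alone). Their adjusted p was 2.13e-10 to 3.52e-09, and 0.47 to 0.548 with an estimated correlation. Among the list tests chosen after values were seen, immediate early genes lay above 0 for 23 of 27 members, with a mean of 0.26. Ribosomal protein, glucocorticoid-responsive and mitochondrially encoded genes did so for 48 of 48, 13 of 14 and 11 of 13. Rod phototransduction genes lay below 0 for 20 of 22. These lists passed camera at adjusted p values of 3.06e-06 to 0.033, but none did with an estimated correlation (0.385 to 0.784). The shares of the classes differ between the pools, and these sums carry that difference. Within corneal or conjunctival epithelium-like cells, a class added after seeing the data, the log2 fold change was -5.947 for Prss22 and -7.044 for Chac1. The log2 ratio of that class's share of cells was -0.4907. These values argue against the share of that class as the source of the fall of these 2 genes. The mix of cells within the class is left open. With all cells summed, the count was 30 without saline replicate 2, 7 without saline replicate 3, and 1 without saline replicate 1, tropicamide replicate 1 or tropicamide replicate 3. Prss22 passed without each library, and Chac1 lost its call without saline replicate 1 or any 1 tropicamide replicate, at edgeR adjusted p values of up to 0.19.

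The genes set beforehand for this question were the muscarinic receptors, the targets of tropicamide, and Egr1, an early response gene linked to eye growth in experimental myopia. Egr1 fell in Müller glia-like cells from 2189 ± 117 to 1372 ± 378 CPM (SD, n = 3 pools per group; edgeR adjusted p = 0.0299), a call that ended without 5 of the 6 libraries, all but tropicamide replicate 2, at adjusted p values of up to 0.206. Its log2 fold change was -0.94 ± 0.30 in rods (edgeR adjusted p = 0.14), -0.73 in retinal pigment epithelium-like cells, -0.48 in fibroblast-like cells, -0.36 in B2, -0.18 in B5, -0.10 in endothelial-like cells, 0.12 in cone bipolar-like cells and -0.02 with all cells summed, none of which passed. Chrm3 was tested in 6 classes and in all cells and did not pass in any, with log2 fold changes of -0.27 to 0.38 and levels of up to 474.7 ± 129 CPM in the cone bipolar-like cells of the saline pools. Chrm2 did not pass in endothelial-like (0.98 ± 0.42, edgeR adjusted p = 0.788) or cone bipolar-like cells (-0.48 ± 0.38, adjusted p = 0.997), and Chrm1 and Chrm2 stood at 0.693 and 9.69 CPM in the tropicamide pools with all cells summed without passing.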

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

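The test of rod phototransduction genes in other classes, the tests within clusters B10 and B20, and Camk2b and Bola2 as named genes were chosen after results had been seen.

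The response to tropicamide differed between Müller glia-like cells and rods for 5 of 6716 genes in a limma test of the difference itself. Cxcl1, Fbxl18 and Rnaseh2a were more negative in Müller glia-like cells, by -3.20 (adjusted p = 0.04), -2.21 (adjusted p = 0.00975) and -2.16 (adjusted p = 0.0407) on the log2 scale in limma. Camk2b, a calcium-dependent kinase gene, and Bola2, an iron-sulphur protein gene, were more positive, by 1.93 (limma adjusted p = 0.0234) and 1.35 (limma adjusted p = 0.04). Camk2b rose by 2.06 in Müller glia-like cells (edgeR adjusted p = 0.0424), a call lost without tropicamide replicates 1, 2 and 3 in turn (edgeR adjusted p of 0.189, 0.119 and 0.184) and not tested without a saline one, and Bola2 did not pass (1.21, edgeR adjusted p = 0.0784). In the 6 other classes limma found 0 genes whose change differed from that in rods.

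Of the classes too small for the comparison of shares, 4 had more cells in every tropicamide pool than in any saline pool. The lowest tropicamide and the highest saline share were 0.175% and 0.173% of cells for Schwann-like cells (59 and 25 cells in all), 0.141% and 0.122% for ciliary or iris epithelium-like cells (61 and 19), 0.0795% and 0.0713% for cluster A26 (38 and 11), and 0.0442% and 0.0115% for erythroid-like cells (22 and 2). These shares were not tested.

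In Müller glia-like cells ribosomal protein, rod phototransduction and mitochondrially encoded genes were higher after tropicamide. Within cluster B10 alone the mean log2 fold change was 0.156 for the ribosomal protein genes, against 0.642 in the class, and 0.104 for the mitochondrially encoded genes, against 0.641. The larger share of the low-depth cluster B20 in the tropicamide pools may therefore account for much of the ribosomal part. It does not account for the rod genes, which stood at 0.811 within B10 against 0.833 in the class. Within B20 alone, however, their mean was -0.27, with 1 of 14 members above 0. There the list passed camera in the opposite direction (adjusted p = 0.00037, or 0.595 with an estimated correlation). Free RNA from rods would lower the ribosomal protein genes, whose mean CPM in rods was 0.659 times that in the Müller glia-like cells of the saline pools. For the rod genes free RNA stays open, since their mean was above 0 in 4 of the 6 other classes. A response of the glia to the drops also stays open and was not tested apart from these.

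The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 1902 genes in rods (highest other split 0), 148 in Müller glia-like cells (1), 5 in fibroblast-like cells (0), 9 in B5 (1), 4 in B2 (2), 3 in retinal pigment epithelium-like cells (3) and 2 with all cells summed (0). It gave 0 in endothelial-like cells in edgeR (highest other 4; 692 at an unadjusted p under 0.05, 21 in DESeq2) and 0 in cone bipolar-like cells (highest other 6; 265 and 1). Of the class and list pairs 92 passed, and 75 in the highest other split. The number of splits with a count as large, the real one included, was 1 for rods, Müller glia-like cells, fibroblast-like cells, B2, B5, all cells and the pairs, 2 for retinal pigment epithelium-like cells, and 10 for endothelial-like and cone bipolar-like cells.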

How the results depend on the processing

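The restrictions of rods, Müller glia-like and endothelial-like cells to some of their clusters, of rods to cells matched in UMIs and to genes at least as high in rods, and the 6 classes with fewer cells, corneal or conjunctival epithelium-like cells among them, were chosen after seeing the data. The other alternatives were planned. Where no cause is given below, the cause was not tested.

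Counting a gene once per class, of the 116 named genes that passed 38 kept their direction and their side of the threshold under every setting run. Over 1959 values of 151 named genes, 1548 kept both, 343 lost the call, 51 gained it and 17 changed sign. Of genes that passed, only Gnat1 and Gngt1 in Müller glia-like cells changed sign, to -0.68 and -0.51 in cluster B20 only. Chrm3, which never passed in the full data, changed sign in cone bipolar-like cells without doublet removal (-0.20) and in endothelial-like cells in cluster B6 only (-0.21) and without doublet removal (-0.0068). Egr1 rose above 0 in endothelial-like cells in cluster B6 only (0.20), without passing. With 1 library left out Chrm3 ranged from -0.69 to 0.51 in Müller glia-like cells, -0.53 to 0.0012 in B2, -0.16 to 0.21 in cone bipolar-like cells, -0.0632 to 0.35 in endothelial-like cells and -0.81 to 0.78 in fibroblast-like cells, and Egr1 from -0.12 to 0.13 with all cells summed.

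The count of genes moved by more than 1.5 times in many classes. The DESeq2 test gave 538 genes with all cells summed, 30 in B2, 20 in B5, 1 in cone bipolar-like, 21 in endothelial-like, 148 in fibroblast-like and 177 in corneal or conjunctival epithelium-like cells. Without the low-count filter edgeR gave 4, 79, 66, 21, 120, 467 and 426 in the same order, 246 in Müller glia-like and 15 in retinal pigment epithelium-like cells. The stricter cell filter gave 64 in Müller glia-like and 6 in retinal pigment epithelium-like cells, and leaving doublets in gave 1 in cone bipolar-like cells and 0 in fibroblast-like cells in edgeR (1650 at an unadjusted p under 0.05 and 148 in DESeq2 with doublets removed). Cluster A0 only gave 1194 in rods, B10 only 44 and B20 only 0 in Müller glia-like cells in edgeR (15 at an unadjusted p under 0.05, 0 in DESeq2), and B6 only 3 and B9 only 7 in endothelial-like cells; these hold fewer cells.

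With 1 library left out, which leaves fewer samples, the count ranged from 529 to 2729 in rods, 4 to 205 in Müller glia-like cells, 0 to 15 in B2, 0 to 20 in B5, 0 to 19 in cone bipolar-like cells, 0 to 31 in endothelial-like cells, 0 to 236 in fibroblast-like cells, 3 to 20 in retinal pigment epithelium-like cells, 1 to 30 with all cells summed and 21 to 183 in corneal or conjunctival epithelium-like cells. The report names the libraries.

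The replicate numbers were not used to pair the libraries: profiles of the same number in the 2 groups correlated at -0.645 to 0.118 after the group means were removed, and 0 to 2 of the 6 libraries per class lay closest to their own number. With the replicate block the count was 16 in B2, 20 in B5, 4 in cone bipolar-like, 3 in endothelial-like, 2 in fibroblast-like, 10 in retinal pigment epithelium-like and 176 in corneal or conjunctival epithelium-like cells, Chrm3 in cone bipolar-like cells was -0.000847, and the log2 ratio of rod bipolar-like shares -0.0297.

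Of 92 class and list pairs, 0 passed with an estimated correlation and 0 with fry, whose smallest adjusted p were 0.47 and 0.16. The other settings gave 67 to 113 pairs, and none of 598 values of 46 lists changed sign. Restrictions to some clusters of a class were not among these settings. In Müller glia-like cells the rod phototransduction list changed sign in cluster B20 only, from 0.833 to -0.267. There it passed camera in the opposite direction (adjusted p = 0.00037, or 0.595 with an estimated correlation).

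In shares, edgeR on cell numbers passed retinal pigment epithelium-like (log2 ratio 1.93) and melanocyte-like cells (2.36), each with an adjusted p of 0.00926, and with the replicate block neither passed, at 0.0566 for both. The other settings gave 0.3 to 0.8. With rods left out of the denominator the log2 ratio changed sign for amacrine-like (-0.59), cone-like (-0.17), fibroblast-like (-0.35), pericyte-like (-0.26), rod bipolar-like (-0.78) and smooth muscle-like cells (-0.12), and without doublet removal for rod bipolar-like cells (-0.11). With 1 library left out it ranged from -0.59 to 0.72 for amacrine-like, -0.44 to 0.26 for cone bipolar-like, -0.0041 to 1.04 for pericyte-like, -0.38 to 0.31 for rod bipolar-like and -0.0193 to 1.499 for smooth muscle-like cells. In simulated data edgeR recovered 43.3% of 2-fold changes in cone bipolar-like and 23.9% in corneal or conjunctival epithelium-like cells, and what part depth has in this was not tested.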

Other observations

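The genes, the gene family, its test without the members named in the text and the tests of free RNA and of UMIs per rod in this part were chosen after values had been seen, as were the 6 classes with fewer cells and their splits. The tests within the largest rod cluster, of the epithelial layers and without 1 pool were written before their own results.

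In corneal or conjunctival epithelium-like cells, the surface lining of the eye that meets the drops, Isg15, an interferon-induced gene, fell from 181.9 ± 21.2 to 12.3 ± 3.82 CPM (SD, n = 3 pools per group; log2 fold change -3.89 ± 0.28, edgeR adjusted p = 0.000341). Gadd45b, a stress response gene, fell by 2.67 (edgeR adjusted p = 0.000422), the protease gene Prss22 by 5.95 (edgeR adjusted p = 0.00116), and Fth1, the ferritin heavy chain gene, by 2.91 (edgeR adjusted p = 0.00181). Chac1 changed by -7.04 ± 0.60 (edgeR adjusted p = 0.00146). Prss27, Slc5a1, Il36g and Irf1 fell by 4.23, 3.77, 4.01 and 2.12. Spink7, a protease inhibitor gene, rose by 3.13 and Eda by 1.45. Of 8454 genes 69 passed, 3 higher and 66 lower, and DESeq2 passed 177. The count was 26 without tropicamide replicate 1, 21 without tropicamide replicate 2, 36 without tropicamide replicate 3, 183 without saline replicate 2 and 131 without saline replicate 3. Isg15, Gadd45b, Prss22, Chac1, Fth1, Prss27, Slc5a1, Il36g and Irf1 passed without each library, while Spink7 and Eda reached an adjusted p of 0.121 and 0.131 in edgeR. The class held 33, 42 and 13 cells in the tropicamide pools and 44, 25 and 41 in the saline pools.

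Fewer cells of the differentiated layers may lie behind the genes called lower. Their 13 markers had a mean log2 fold change of -0.752, against a median of -2.452 for the genes called lower. Of the 13 markers 8 lay below 0, and the 66 genes called lower hold none of them. The genes called lower do hold other epithelial genes, such as the late cornified envelope gene Lce3a (from 2182 to 0 CPM). Another is the keratin gene Krt23 (from 93.9 to 3.31 CPM), which lost its call without 1 library. The absence of the 13 markers among the calls therefore does not settle the question. The 9 markers of the basal layer had a mean of -0.25, with 7 below 0. The estimate over samples for the differentiated layers was -1.03 with a standard error of 0.203. The bound set beforehand took the mean less 2 standard errors over samples, and -0.752 cleared it, against that explanation. The bound was wrong in that this standard error belongs to the estimate over samples, and -1.03 less 2 of its own standard errors did not clear it, so the explanation is left open. Without tropicamide replicate 3, the pool with 13 cells, 33 of the 66 genes were still called lower and all 66 were still below 0. This sits exactly at the bound set beforehand and, as written, meets the outcome against that pool as the cause. In all, 35 genes were called lower without tropicamide replicate 3, against 26 without replicate 1 and 21 without replicate 2. These values argue against that pool as the only source of the genes called lower, and how much it adds is left open. An effect of the drops on the ocular surface was not tested apart from these.

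In rods the cytosolic aminoacyl-tRNA synthetases, which load amino acids onto tRNAs, were lower as a family after tropicamide. Of 20 members 18 lay below 0 and 12 fell (14 adjusted over the list alone), with a mean of -0.32. Yars, Cars and Iars prompted the choice of the family, and Aars, Mars1 and Gars fell by 0.54, 0.56 and 0.48. Among the 14 members without these 6, 12 lay below 0 and 6 fell (6 adjusted over the list alone), with a mean of -0.16 and an adjusted camera p of 0.000151. With an estimated correlation it did not pass (adjusted p = 0.14). The photoreceptor genes Nr2e3 and Rgs9bp rose by 0.54 and 0.51. Of stress genes Herpud1, Asns and Trib3 fell by 0.56, 0.78 and 0.49, and Pdia6 and Pdia3 rose by 0.33 and 0.28. The unfolded protein response list did not pass, with 2 members that rose and 3 that fell (4 and 4 adjusted over the list alone) and an adjusted camera p of 0.543. Asns, Trib3 and Pdia3 each lost the call in edgeR without any 1 library but saline replicate 3, at adjusted p values of up to 0.0879, 0.106 and 0.18, and Pdia6 without tropicamide replicate 2 (edgeR adjusted p = 0.0719). The family's mean was -0.14 to 0.08 in the 7 other classes, where no member passed in edgeR. Whether this mean differs from that in rods was not tested. The limma test of single genes called no member of the family as different between rods and another class.

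A different mix of rod clusters is argued against by the mean within the largest rod cluster, -0.353 against -0.316 over all rods. For free RNA from other cells, genes at least 3 times higher outside the rods had a median of 0.142 in rods and the family one of -0.259. This was the outcome written, after values had been seen, as against that explanation. It cannot decide, since added free RNA would lower genes scarcer outside the rods, and the family's level there was not compared. In the tropicamide pools Ttr stood at 83.6 to 200.1 CPM in rods and 77680 to 84620 in retinal pigment epithelium-like cells. Dcn stood at 86.6 to 154.7 CPM in rods and 13490 to 16890 in fibroblast-like cells. Such small levels in rods argue against dilution by RNA of these classes as the source of the family's fall. Free RNA of other kinds is left open. The median UMIs per rod were lower after tropicamide, 2011 to 2043 against 2137 to 2279. Among 5942 rods per pool drawn to the same number in each bin of UMIs, where the medians were 2178.5 to 2183.5 and 2182.5 to 2186, the family's mean was -0.317, which argues against fewer UMIs per rod as the cause. A response of the rods to the drops may be a biological explanation, as a hypothesis that was not tested apart from these.

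Of the other classes with fewer cells, edgeR passed 1 gene in cone-like cells (Ttr, a retinal pigment epithelium transcript, which rose by 2.14 and was higher after tropicamide in rods too), 1 in amacrine-like cells (Vim, which fell by 3.04), 1 in rod bipolar-like cells, a gene with a clone-like name, and 0 in smooth muscle-like and T or NK cells (255 and 44 at an unadjusted p under 0.05, and 0 in DESeq2 for both). The 10 splits of the libraries are too few for a share under 0.05. The real and the highest other count were 69 and 1 in corneal or conjunctival epithelium-like cells, 1 and 1 in cone-like cells, 1 and 3 in amacrine-like cells, 1 and 1 in rod bipolar-like cells, 0 and 10 in smooth muscle-like cells and 0 and 5 in T or NK cells. Splits with a count as large numbered 1, 4, 3, 2, 10 and 10 in that order, the real one included. The count in cone-like cells was 0 without saline replicate 2, 8 without saline replicate 3, and 2 without saline replicate 1 or tropicamide replicate 1. That in amacrine-like cells was 20 without saline replicate 1 and 0 without saline replicate 2 or 3 or tropicamide replicate 1 or 3. It was also 0 with the replicate block and 0 with doublets left in, 71 without the low-count filter and 11 in DESeq2. That in rod bipolar-like cells was 3 without saline replicate 1, 4 without saline replicate 3, 5 without tropicamide replicate 1, 11 without tropicamide replicate 2 and 0 without tropicamide replicate 3. DESeq2 passed 0 genes in cone-like and 0 in rod bipolar-like cells, where 311 and 317 had an unadjusted p under 0.05 in edgeR.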
